A study of Drosophila melanogaster with 3 samples.

How the data were processed

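Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done, per the labels, on whole Drosophila melanogaster embryos aged 0 to 24 h. The embryos came from a transgenic line that expressed the nuclear receptor Hr51 fused to eGFP, and the fusion protein was precipitated with an antibody against GFP, per the description in the labels. Another field of the labels gives the antibody as Hr51. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the assemblies used were dm6 and dm3. The 3 samples are biological replicates of 1 group. The sample table holds no control library, and the possible control experiment that the labels name was not analysed here.

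The analysis used 10 deposited peak lists, 5 for dm6 and 5 for dm3. For each build these were a relaxed list of 30000 peaks for each replicate and for the pooled reads, and an optimal list filtered by the irreproducible discovery rate (IDR). Per the README text deposited with the samples, each relaxed replicate list was made from that replicate's alignment and 1 further file. The pooled list was made from the 3 alignments and the same further file, and the IDR list from the replicate and pooled lists. That file was read as the control because the same text gives it as an input of the control-normalized track, although the text does not call it a control. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists give each peak a signal value, made by the authors' peak caller and with no common scale between lists, so it was used only to rank or filter peaks within a list. They also give a deposited −log10 q value per peak, which was not used in the comparisons. The pooled relaxed lists are labelled as peaks and background, for input to IDR. In dm6 the lowest −log10 q was 0.0686 in the pooled list and 3.00 in the IDR list. Entries of the pooled lists, called peaks throughout, therefore include background. In both builds the IDR list held exactly the peaks of highest signal in the pooled list, 3496 in dm6 and 3369 in dm3. The files give no read counts, so the depth of each sample is unknown and the intervals printed cover the counting of peaks only.

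All comparisons used dm6 unless stated. The sequence was Release 6 of the genome, arms 2L, 2R, 3L, 3R, 4 and X, and the annotation was Ensembl release 115 (BDGP6.54, FlyBase 6.54). No dm3 reference was used and no coordinates were converted between builds. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

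Replicate agreement was the share of IDR summits within 150 bp of a summit among each replicate's 3496 peaks of highest signal, and the same share between pairs of replicates. Chance values came from 200 circular shifts of summits along each arm. Each IDR summit was assigned to the earliest that applied of promoter (within 500 bp of an annotated transcription start site, TSS), 5' UTR, coding exon, 3' UTR, other exon, intron (sequence of a gene in no exon) and intergenic sequence. TSSs were those of all annotated genes except transposable elements. An earlier version had used protein-coding TSSs only. Both shares had been seen when the wider set, which follows the written plan, was made the main one. Class shares were compared with 10000 circular shifts in two-sided tests, and with the 25684 pooled peaks that overlapped no IDR peak. The shifts cover whole arms, pericentromeric sequence included.

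A gene counted as having a promoter peak when an IDR summit lay within 500 bp of its TSS. Each of 18 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test, and 13 list symbols had no match in the annotation. Each of 22 consensus sequences, and each of the 6-mers collapsed with their reverse complements, was sought within 50 bp of summits. The comparison windows had the same width and lay 500 bp to either side. The test was the two-sided exact McNemar test on discordant peaks, run for each flank, and the larger p was kept. Signal at promoter and other peaks was compared by a two-sided permutation test on mean rank with 100000 resamples. Intervals for the difference in half-site share came from 2000 bootstrap resamples of peaks. All p-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. These p-values are across peaks or genes, which are not independent replicates, and no test over the 3 replicates was run. An exact sign test of 3 values cannot give a p below 0.25, and tests that assume a normal distribution were not used with so few values.

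The tests, gene lists, consensus sequences, named-gene rule and most alternative settings were fixed before the data were examined. By that rule the text names Hr51, the protein-coding gene with the TSS nearest to each of the 25 IDR summits of highest signal, and up to 4 members of each list with a promoter peak, those of highest signal. Gene lists, consensus sequences and the Hr51 region had been looked at before the final calculations were written. The alternatives changed the overlap rule, the number of peaks, the promoter window, the background, the flanks and the build, and left out each replicate in turn. For replicate agreement, the values of the left-out replicate were dropped. For classes, gene lists, consensus sequences and 6-mers, the IDR peaks found in the top lists of both other replicates were kept. These were 2074, 2163 and 2374 peaks without replicates 1, 2 and 3. The IDR list was not remade, so the left-out replicate still shaped its peaks. Alternatives with protein-coding TSSs only, for 6-mers without each replicate, and for the named genes were chosen after seeing the data.

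Further tests were added after the results were seen. They compared 8 gene families, chosen by symbol, with other genes by Fisher's exact test, and the 2 lists that passed with 10000 random lists matched on coding length. They also compared each consensus that was higher at summits, and the half-sites, with up to 200 reorderings of its letters. Around Hr51, promoter sequence and peaks in coding exons within 20 kb were ranked against the same window around all protein-coding genes. The same ranking of all peaks had been fixed beforehand.

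The tests were also run on simulated data. With no planted effect, promoters were called in 1 of 20 runs, a list in 7 of 200, the half-site in 0 of 10 and a signal difference in 2 of 40. Planting 10% of peaks at TSSs was called in 20 of 20 runs, a 3-fold rate in a list of 25 genes in 198 of 200, and a shift of signal by 0.2 SD in 40 of 40. An NR2E half-site planted in 2% of windows was called in 5 of 10 runs, and in 5% of windows in 10 of 10. In the half-site runs, sequence further from the peak stood in for the summit windows. The lower G and C content of real summits was therefore not simulated, and these rates may not hold for the real windows.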

Results

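Hr51 (unfulfilled) is a nuclear receptor of the NR2E group, known for its part in the development of mushroom body neurons. The data are peak lists from 3 biological replicates of ChIP-seq for an Hr51-eGFP fusion in whole embryos aged 0 to 24 h. There was 1 group and no control library among the samples, so the comparisons are between replicates, between peaks and genomic background, and between gene groups. Signal is the authors' value per peak and is read here as a rank within a list. The depth of the samples is unknown.

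The strongest peaks lay mostly at promoters and were shared by the 3 replicates. Of the 25 peaks of highest signal in the 3496-peak IDR list, 18 were at promoters, 6 in introns and 1 in intergenic sequence. All 25 were found in each of the 3 replicates, and 24 were among the 100 highest in every replicate. The exception was a peak at X 12751098 to 12751614, which ranked 21 and 16 in replicates 1 and 2 and 154 in replicate 3. It lay within 500 bp of the transcription start site (TSS) of a non-coding gene, and the nearest protein-coding TSS was that of CG4004, 5121 bp away.

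The highest signal, 1778, was at 3L 19590421 to 19590817, with a summit 98 bp from the TSS of CG14100 (FBgn0036889), and ranked 1, 1 and 4 in the replicates. The next, with a signal of 1679, was at 2L 480834 to 481298, 1370 bp from the TSS of cbt (FBgn0043364), a zinc-finger transcription factor gene, but inside an intron of ush. The third, with a signal of 1481, was 35 bp from the TSS of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. Further promoter peaks among the 25 lay nearest to px, Chro (a chromatin protein of polytene interbands), CG1888, CHMP2B (an ESCRT-III subunit), PNPase (a mitochondrial RNA-processing enzyme) and ph-p (a Polycomb group protein). Others lay nearest to mRpL41 and mRpS10 (mitochondrial ribosomal proteins), CenG1A, Shc, Pdrg1, CG8320, GstE13, larp and CG5098. The remaining intron peaks were nearest to CG11050, Lk6 (a kinase of the translation factor eIF4E), CG32772, CG9663 and HmgZ. The intergenic peak was 11911 bp from the TSS of CG13323. At 8 of the 25 peaks, 2 or more protein-coding genes had a TSS within 500 bp, so the nearest gene is a label of position.

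Peaks were found again in each replicate far above chance. Of the 3496 IDR peaks, 81.9%, 79.5% and 74.4% had a summit within 150 bp among the 3496 highest peaks of replicates 1, 2 and 3, a mean of 78.6% ± 3.82 (SD, n = 3). Shifted summits gave 0.787%, 0.764% and 0.781%, and at most 1.29%. All 3 replicates held 1838 of the peaks (52.6%), 2 replicates 1097 (31.4%), 1 replicate 538 (15.4%), and 23 were in none of the 3 top lists. Between pairs of replicates, 70.2% of peaks were shared by replicates 1 and 2, 63.7% by 1 and 3, and 60.7% by 2 and 3. Spearman correlations of signal across IDR peaks, which are not independent replicates, were 0.698, 0.552 and 0.495 for these pairs. The IDR list was made from these same replicates, so its agreement with them is not independent of the selection.

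**Figure D1:**
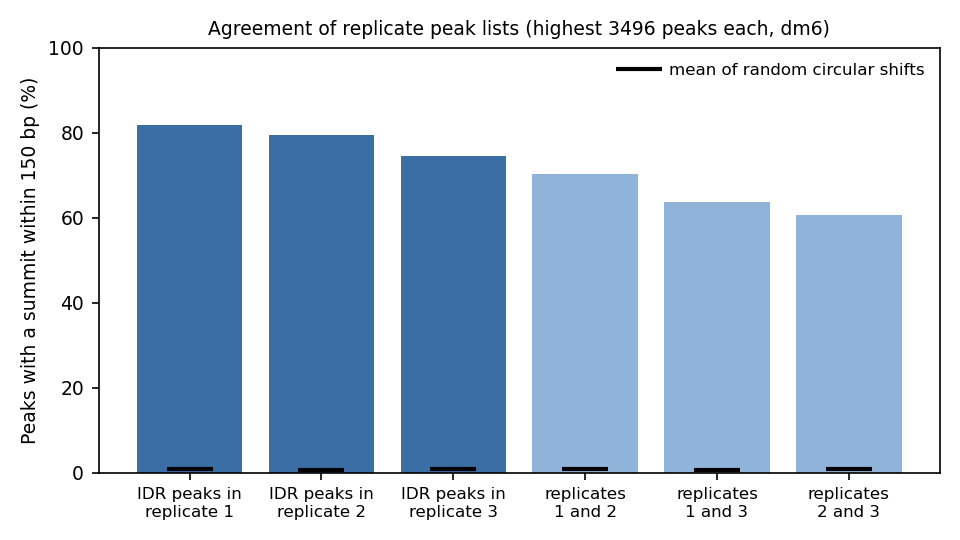
Share of peaks (%) found within 150 bp in each replicate's highest peaks and between pairs of replicates, with the chance level from shifted summits. The 3 replicates hold between 74.4% and 81.9% of the IDR peaks, and the mean of the shifts is under 1%.

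Promoters held most of the peaks, and coding exons almost none. Promoters held 2154 IDR peaks, 61.6%, against 13.6% by chance (95% of shifts gave 12.2% to 15.2%), a ratio of 4.53. In the replicates' own top lists the share was 61.4% ± 1.16 (SD, n = 3). Introns held 26.6% against 39.4% by chance, and intergenic sequence 9.75% against 27.3%. Only 14 peaks, 0.400%, were in coding exons against 13.7% by chance (0.257%, 1.46% and 0.772% in the replicates' own top lists), and 3' UTRs held 0.543% against 4.40%. These 5 classes had an adjusted permutation p of 0.0003, the unadjusted 0.0002 being the smallest that the shifts can give. The 5' UTRs (0.486% against 0.778%, adjusted p = 0.0604) and other exons (0.629% against 0.816%, adjusted p = 0.300) did not pass the permutation test. The 5' UTR share passed without replicate 1 (0.289%, permutation adjusted p = 0.0114) and without replicate 3 (0.337%, permutation adjusted p = 0.0154). Such sets hold the IDR peaks found in the top lists of both other replicates, and the IDR list was not remade. The median distance from summit to TSS was 215 bp, with 33.4% of summits within 100 bp and 48.6% within 200 bp.

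Among the 25684 weaker pooled peaks that overlapped no IDR peak, 26.9% were at promoters and 21.7% in coding exons. By rank in the pooled list, the promoter share was 62.1% in ranks 1 to 3000 and 18.8% in ranks 27001 to 30000, and the coding exon share 0.267% and 25.5%. When all 30000 pooled peaks were used, coding exons held 18.7%, above chance, so their low share holds for the stronger peaks only. Within the IDR list, signal was higher at promoters (median 122, n = 2154) than elsewhere (median 111, n = 1342). The mean ranks differed by 193, with a permutation p of 1e-05, the smallest that the resamples can give. The promoter share was 72.6% in the decile of highest signal and 59.4% in the lowest.

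**Figure D2:**
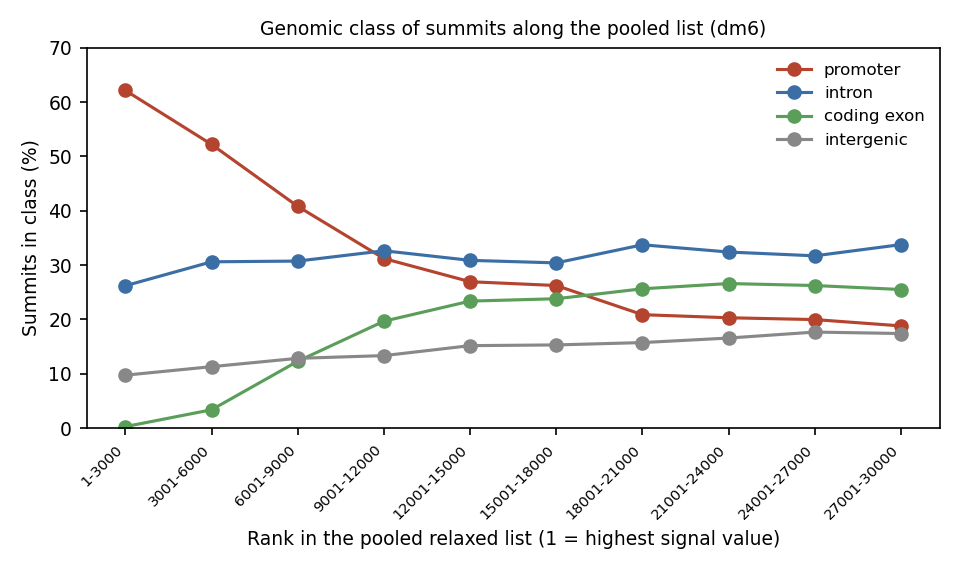
Share of pooled peaks (%) in each genomic class by rank of signal, in bins of 3000 peaks. The promoter share is 62.1% in the first bin and 18.8% in the last, and the coding exon share 0.267% and 25.5%.

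Genes for ribosomal proteins and general housekeeping functions carried promoter peaks in the IDR list more often than other genes. In all, 2669 of 13945 protein-coding genes (19.1%) had a promoter peak in the IDR list, and 2618 ± 71.1 (SD, n = 3) in the replicates' top lists. Cytosolic ribosomal protein genes had them at 60 of 85 (70.6%, against 18.8% of other genes; Fisher's exact test, adjusted p = 1.14e-23), and in the replicates at 58 ± 5.29 (SD, n = 3). The strongest were at RpS27 (FBgn0039300; signal 596, rank 50), RpL7 (590, rank 52), RpL34b (459, rank 94) and RpL23A (428, rank 108). Genes for transcription, splicing, the proteasome and other housekeeping functions had them at 18 of 39 (46.2%; Fisher's exact test, adjusted p = 0.00101), and in the replicates at 19.3 ± 2.08 (SD, n = 3). Among these were the glycolytic gene Gapdh2 (FBgn0001092; signal 338, rank 180), the elongation factor gene eEF1alpha1, the tubulin gene alphaTub84B and the RNA polymerase gene Polr2B. Among the 1748 peaks of higher signal, the housekeeping list no longer passed, with 10 genes and an adjusted p of 0.0713, although its share was 25.6% against 10.9% of other genes. Coding exons were examined in the whole pooled list, weaker peaks and background included, so the shares there cannot be set beside the IDR promoter shares. In that list, promoter peaks were at 95.3% of ribosomal protein genes and 92.3% of housekeeping genes, against 53.9% and 54.1% of other genes. A peak in a coding exon was at 20% of ribosomal protein genes, against 6.43% of genes in random lists matched on coding length. For housekeeping genes the coding exon share was 53.8% against 27.7%. The adjusted p was 0.0004 and 0.0006, from 10000 random lists, in a test chosen after the list results were seen.

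The other 16 of the 18 lists did not pass after adjustment. Of the 18, 0 had promoter peaks less often than other genes after adjustment, and 5 had an unadjusted p under 0.05 by Fisher's exact test. Circadian clock genes (8 of 20, among them sgg, Fbxl4, ctrip and Sik3) and Notch pathway genes (8 of 20, among them numb, E(spl)m3-HLH, Su(H) and neur) each had an adjusted p of 0.141 by Fisher's exact test. The Notch list had 4, 3 and 3 genes without replicates 1, 2 and 3, and the circadian list 5, 5 and 6, in sets of fewer peaks. With all pooled peaks, background included, the Notch list passed as more frequent (19 of 20, Fisher's exact test, adjusted p = 0.000793). It also passed in a test of IDR peaks anywhere in the gene against length-matched lists (12 of 20, permutation adjusted p = 0.0372). Fat body and hemocyte markers had 0 of 20 (Fisher's exact test, adjusted p = 0.130), and Hox genes 0 of 8. Nuclear receptor genes had 6 of 21, with Hr96 (FBgn0015240; signal 322, rank 209), Eip75B (272, rank 317), ERR and usp. Ecdysone genes had 4 of 27 (Eip75B, hid, usp and tai), and the mushroom body list 4 of 26. The latter were dnc (FBgn0000479; a cAMP phosphodiesterase gene, signal 407, rank 121), Hr51, Imp and so, with an adjusted p of 0.806 by Fisher's exact test. Without peaks within 20 kb of Hr51, the tagged gene, the mushroom body list had 3 of 26 and the nuclear receptor list 5 of 21, and neither passed.

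Neuroblast and temporal factors had 3 of 27 (elav, a neuronal RNA-binding protein gene with signal 478 and rank 84, numb and brat). Axon guidance genes had 8 of 36, with Abl, Ten-a, wnd and caps, and synaptic genes 4 of 31, with elav, dlg1, sei and Shab. Of these, Shab had a promoter peak in the top list of replicate 1 only. Glial markers had 3 of 13, namely moody (FBgn0025631; a receptor of the blood-brain barrier, signal 434, rank 105), pnt and htl. Muscle and mesoderm markers had 5 of 24, with sls, tin, htl and how, and epidermis and trachea markers 5 of 17, with crb, Cht7, trn and trh. Of these, trh had a promoter peak in the top list of replicate 3 only. Gut markers had 4 of 14 (fkh with signal 333 and rank 187, tin, Hnf4 and grn), and germline markers 4 of 11 (bgcn, tud, piwi and zpg). Segmentation genes had 4 of 28, with bcd, nkd, ptc and wg, the last 2 in the top list of replicate 3 only. With any replicate left out, in sets of fewer peaks, 2 of 28 remained.

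**Figure D3:**
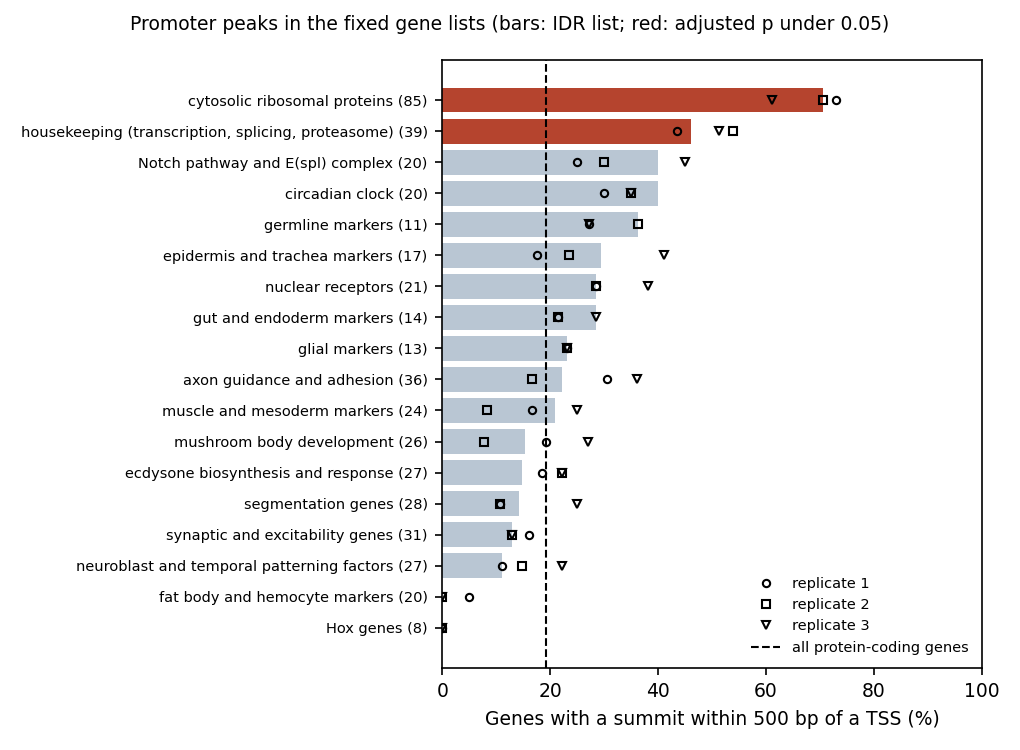
Share of each list's genes (%) with an IDR summit within 500 bp of a TSS (bars), with each replicate's top list as points and the share of all protein-coding genes as a dashed line. Cytosolic ribosomal proteins reach 70.6% and housekeeping genes 46.2%, against 19.1% of all protein-coding genes.

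Summits carried the DREF/BEAF, M1BP and CTCF consensus sequences more often than their flanks, and the half-site of Hr51's own receptor group did not differ from the flanks past the threshold. The DREF/BEAF consensus TATCGATA was at 3.38% of summits and 0.343% of flanks, a ratio of 9.83 (exact test, adjusted p = 1.90e-18), and at 3.17% ± 0.697 of summits in the replicates (SD, n = 3). The M1BP consensus was at 1.09% against 0.114% (exact test, adjusted p = 1.83e-06) and the CTCF consensus at 1.66% against 0.257% (adjusted p = 2.47e-07). The consensus of Su(Hw), an insulator protein as CTCF is, was at 0.315% against 0.172% and did not pass (exact test, adjusted p = 0.602). The Mef2 consensus (5.29% against 2.96%, exact test, adjusted p = 8.06e-05), the homeodomain consensus (7.41% against 5.53%, adjusted p = 0.00885) and the forkhead consensus (3.78% against 2.20%, adjusted p = 0.00470) were higher too. At peaks outside promoters, the DREF/BEAF (ratio 1.14), M1BP (ratio 4), Mef2 (1.60) and homeodomain (1.14) consensuses did not pass, against ratios of 9.83, 9.50, 1.79 and 1.34 for all IDR peaks. The forkhead consensus, with a ratio of 1.71, did not pass among the 1748 peaks of higher signal (ratio 1.82), all pooled peaks (1.17) or promoter peaks (1.36). At peaks outside promoters it passed (ratio 2.43, exact test, adjusted p = 0.0111), as did CTCF (ratio 7.75, exact test, adjusted p = 7.62e-05). With all pooled peaks the homeodomain consensus was lower at summits (ratio 0.775, exact test, adjusted p = 1.91e-13), and Mef2 had a ratio of 0.897 and did not pass (adjusted p = 0.0527). The M1BP ratio was 17 without replicate 1, 18 without replicate 2 and 10.4 without replicate 3, on few flank windows. Against the other pooled peaks the ratios of DREF/BEAF, M1BP and CTCF were 4.13, 3.14 and 2.37, and with all pooled peaks 3.73, 3.72 and 3.28. The other pooled peaks were at promoters less often than the IDR peaks, 26.9% against 61.6%, and promoter position was not matched. DREF/BEAF was at 5.29% of promoter peaks and 0.298% of the remaining IDR peaks, M1BP at 1.67% and 0.149%, and CTCF at 1.25% and 2.31%. The summit windows were poorer in G and C than the flanks, 37.8% against 43.9%. The GAGA consensus was lower, 1.69% against 2.73% (ratio 0.618, exact test, adjusted p = 0.0204). With similar ratios but fewer peaks, it did not pass without replicate 1 (ratio 0.614, exact test, adjusted p = 0.0987) or without replicate 2 (ratio 0.595, exact test, adjusted p = 0.125). It did not pass in 6 further alternatives either, among them all pooled peaks, with a ratio of 1.09.

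The NR2E half-site AAGTCA was at 4.81% of summits and 4.62% of flanks (exact test, adjusted p = 1). The difference was 0.186 percentage points, with a bootstrap 95% interval from -0.586 to 1.06. With all pooled peaks the ratio was 0.899 (exact test, adjusted p = 0.0273). The half-site AGGTCA, shared by many nuclear receptors, was at 1.83% against 2.66% (exact test, adjusted p = 0.537, bootstrap interval of the difference from -1.40 to -0.257). This p comes from the flank with the larger p, whereas the interval is for the mean of both flanks and lies wholly on the negative side. The direct repeat of the half-sites was at 0 summits. AGGTCA passed as lower with 100 bp windows (exact test, adjusted p = 0.0194) and against the other pooled peaks (Fisher's exact test, adjusted p = 0.00955). Of all 6-mers, 340 were higher and 507 lower at summits. Of the higher ones, 53.5% held 0 or 1 G or C, against 11.0% of all. The lowest p-values were those of TTAAAA (26.5% against 13.6%), CGATAG (8.72% against 2.06%), TATCGA (10.8% against 3.82%) and ACACTG (10.8% against 3.89%). CGATAG and TATCGA overlap the DREF/BEAF consensus, and ACACTG the M1BP consensus. Without replicate 1, 223 6-mers were higher and 314 lower.

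**Figure D4:**
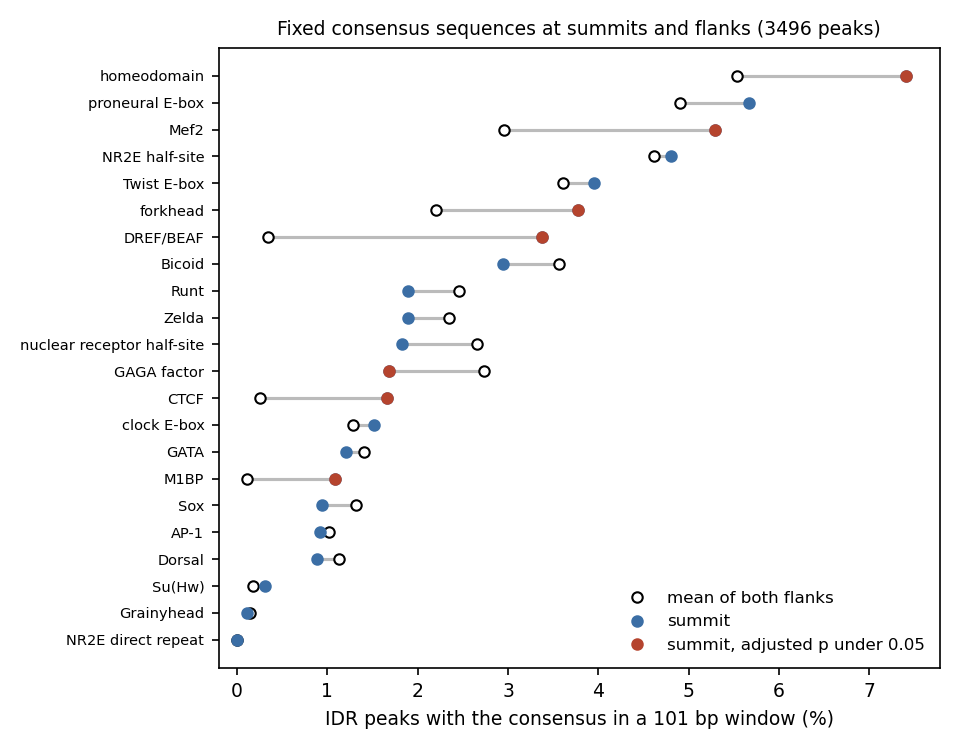
Share of IDR peaks (%) with each fixed consensus in a 101 bp window at the summit and at flanks 500 bp away. DREF/BEAF is at 3.38% of summits and 0.343% of flanks, and the NR2E half-site at 4.81% and 4.62%.

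The Hr51 gene itself (FBgn0034012, 2R 15331325 to 15339384, plus strand) lay in a region dense in peaks. Within 20 kb of it were 10 IDR peaks and 36 peaks of the pooled list, which includes background. The density of pooled peaks was at the 99.6th percentile of protein-coding genes. The replicates had 31, 28 and 33 peaks there, at the 98.6th, 96.9th and 98.8th percentiles. The peak nearest to the gene's TSS had its summit at 15330987, 338 bp away, with a signal of 118 and rank 1766. The top lists of replicates 1 and 3, but not 2, held a summit within 500 bp of this TSS. An overlapping IDR peak, with its summit at 15330764 and 561 bp from the TSS, had a signal of 195 and rank 675. The strongest peaks in the region, chosen after their values were seen, were at 15339675 (signal 494, rank 80, intergenic), 15349997 (signal 383, rank 138) and 15329430 (signal 377, rank 147, intergenic). The middle one of these was classed as promoter, by a class that counts non-coding genes too, and lay inside unc-5, a netrin receptor gene. The labels describe a transgenic line with an insertion that targets Hr51, and do not say in how many copies the locus was present.

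**Figure D5:**
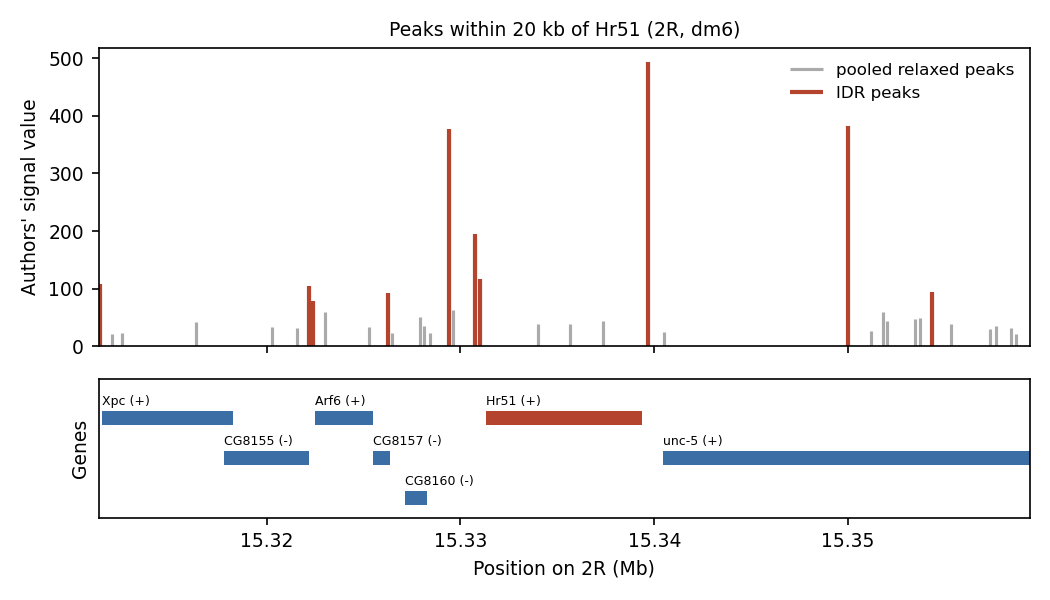
Peaks around Hr51 on 2R (position in the genome, dm6) with their signal in the IDR list, and annotated genes. The strongest peak, at 15339675, has a signal of 494, and the one nearest to the TSS of Hr51, at 15330987, has 118.

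The chromosome arms carried similar densities of IDR peaks, except chromosome 4. There were 28.1 peaks per Mb on 2L, 26.7 on 2R, 25.5 on 3L, 25.9 on 3R and 25.5 on X. Chromosome 4, which is largely heterochromatic, had 8.16 per Mb, 11 peaks or 0.315% of the list (exact 95% interval 0.157% to 0.562%). The pooled list also had fewer there, 95.7 per Mb against 208 to 231 on the other arms. Replicate 1 had 259 relaxed peaks on chromosome 4, and replicates 2 and 3 had 139 and 128. The IDR list held 3496 peaks in dm6 and 3369 in dm3, 127 more in dm6 (3.77%).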

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

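The tests of promoter sequence, coding exons, other gene families and reordered sequences below were chosen after the result was seen, as was the use of the planned matched lists to test an explanation, and those of the density around Hr51 and of the 2 gene lists were fixed before. No biological explanation was tested, since the samples form 1 group.

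In dm3, 41 of the 30000 pooled peaks lay on 6 contigs outside the chromosome arms, which the comparisons do not use. They are given because they are peaks in data not otherwise used, and were not tested against a background. The replicates had 62, 76 and 61 such peaks. The highest ranked 6075 in the pooled list, and 0 of the 3369 IDR peaks lay there.

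Peaks were dense around Hr51, with a density at or above the 96.9th percentile in every replicate. The share of promoter sequence in the region was at the 22.9th percentile, which argues against a region dense in transcription start sites. This test replaced another, the density of peaks outside promoters, which had percentile 97.2 in the pool and 94.4, 92.6 and 97.5 in the replicates, and decided nothing. Extra copies of the locus carried by the tagging transgene may account for the density, although the labels do not give the copy number. If extra copies raised coding exons as well, peaks there would be dense, and their pooled density, at the 92.4th percentile (65.1, 87.0 and 65.2 in the replicates), leaves that open.

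Ribosomal protein and housekeeping genes had promoter peaks more often than other genes. Matching on the number of transcription start sites and gene length left an adjusted p of at most 0.0054 for both lists, which argues against these as the whole cause. Non-specific signal at highly transcribed genes stays open: the larger adjusted p of the 2 lists, 0.00101, is the pattern itself and does not favour it, and no expression values or control library were analysed here. The 2 families taken for it as highly transcribed, respiratory chain genes (19 of 84) and translation initiation factor genes (12 of 44), did not decide it. They did not pass but were not below other genes, with a larger adjusted p of 0.405 by Fisher's exact test. Of all 8 families compared, 1 (mitochondrial ribosomal proteins, 26 of 73) passed as more frequent and 4 as less frequent. Whether signal spread over coding exons accounts for part of the pattern stays open. A pooled peak in a coding exon was at 17 of 85 ribosomal protein genes (20%), and at 12 of the 60 with a promoter peak in the IDR list. Among housekeeping genes it was at 21 of 39, and at 9 of the 18 with a promoter peak. Both lists exceeded lists matched on coding length, but such peaks were no more frequent at genes with a promoter peak than in each whole list. Spread within 500 bp of a start site counted as promoter.

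Several consensus sequences were more frequent at summits, which are low in G and C. Low G and C content was tested by reordering the letters of each consensus. The ratios of DREF/BEAF (percentile 100), M1BP (percentile 100) and CTCF (percentile 100) exceeded those of 200 reorderings each. For DREF/BEAF, whose reorderings had a median ratio of 1.47, this argues against composition as the cause. The reorderings of M1BP and CTCF had median ratios of 0 and 0.5, so the test could hardly have favoured composition there. Reorderings absent from the flanks gave no ratio and were left out, which can lower the comparison for rare sequences. For Mef2 (percentile 47.5), homeodomain (percentile 7.69, of 13 reorderings) and forkhead (percentile 90.5), composition may account for the ratio. The half-sites AAGTCA and AGGTCA were at the 29.4th and 15.6th percentiles of their reorderings.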

How the results depend on the processing

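The alternatives with protein-coding TSSs only, for 6-mers and for named genes were chosen after the result was seen, and all others were fixed before. Promoter enrichment, the ribosomal protein list, the CTCF consensus and the higher signal at promoters kept their direction and side of the threshold in every alternative run for each. The promoter share was 31.9% (all pooled peaks) to 70.2% (1000 bp window), and 59.0% with protein-coding TSSs only. Depth is unknown, and no control library was analysed here. The direct repeat of half-sites, at 0 summits and 0 flanks of the IDR list, gave no ratio to compare with those of 3 alternatives (0.25, 0 and 0), none of which passed. Except for replicate agreement, leaving out a replicate kept only IDR peaks found in the top lists of both other replicates. Those sets are therefore also stricter, and are not a new peak call without that replicate. Unless stated below, the cause of a change was not tested.

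Replicate agreement, 78.6%, was 71.7% with reciprocal overlap, 66.0% at 50 bp, 82.5% for the 1000 highest peaks and 97.7% against whole relaxed lists. Pairwise agreement, 64.9%, was 45.4%, 70.7% and 38.2% at 50 bp, for the 1000 highest and for whole lists, and 60.7% to 70.2% with a replicate left out, highest without replicate 3. A distance of 50 bp can only lower these shares.

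With all 30000 pooled peaks, coding exons (18.7%) and 5' UTRs (1.10%) were above chance, and other exons (0.837% against 0.816%, permutation adjusted p = 0.761) were not distinguished from it. The 5' UTR share was 0.289% to 0.462% with a replicate left out, and passed without replicate 1 (0.289%) and without replicate 3 (0.337%). In the same sets the coding exon share was 0.185% to 0.295% and the 3' UTR share 0.338% to 0.379%, all below chance.

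The number of lists that passed, 2, was 1 among the 1748 peaks of higher signal, 4 with all pooled peaks and 4 with peaks anywhere in the gene or within 1000 bp against length-matched random lists, which changed the background as well. The added lists were Notch (19 genes, adjusted p = 0.000793) and axon guidance (30, 0.00147) with all pooled peaks, by Fisher's exact test. With peaks anywhere in the gene and length-matched lists they were Notch (12, permutation adjusted p = 0.0372) and, as less frequent, synaptic genes (7, 0.0387). Against matched lists, fat body and hemocyte markers passed as less frequent (0, permutation adjusted p = 0.0168). The direction of 13 lists that did not pass turned in 37 alternatives, in each of which the list did not pass either. With all pooled peaks, this held for synaptic (20 genes), segmentation (16), Hox (7), neuroblast (20), mushroom body (19) and ecdysone genes (20). With peaks anywhere in the gene it held for muscle (9), ecdysone (12), mushroom body (12), epidermis (7) and gut genes (5). With a 200 bp window it held for muscle (1), nuclear receptor (3), gut (1) and glial genes (1), and against matched lists for muscle (5), glial (3) and axon guidance genes (8). Among the 1748 peaks it held for ecdysone (4), axon guidance (2), glial (1), germline (1) and muscle genes (2). With a replicate left out, counts were 3 to 4 for axon guidance, 4 to 4 for ecdysone, 2 to 3 for epidermis, 1 to 3 for germline, gut and muscle, and 2 to 4 for mushroom body genes.

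The number of consensuses lower at summits, 1, was 0 among the 1748 peaks, with flanks at 1000 bp and for promoter peaks, 5 with all pooled peaks, 3 against other pooled peaks, and 0 to 1 with a replicate left out. It was 0 without replicate 1 and without replicate 2. The number higher, 6, was 2 outside promoters. Ratios turned in 23 cases, 18 of them past the threshold on neither side. With all pooled peaks they were 0.897 for Mef2, 0.931 for Twist, 0.775 for homeodomain, 0.899 for the NR2E half-site and 1.09 for GAGA. Against other pooled peaks they were 1.10 for AP-1, 1.22 for GATA, 1.10 for Bicoid and 0.846 for proneural E-boxes. Outside promoters they were 0.759 for proneural E-boxes, 1.33 for Zelda and 0.885 for the NR2E half-site. Among the 1748 peaks they were 0.909 for proneural E-boxes and 1.31 for AP-1, and with 100 bp windows 1.07 for GATA and 0.941 for clock E-boxes. Consensuses that did not pass in the IDR list passed in some alternatives. With all pooled peaks (exact tests) these were proneural E-boxes (1.36, adjusted p = 1.61e-15) and clock E-boxes (1.20, 0.0256) as higher, and Bicoid (0.780, 1.54e-06), Dorsal (0.774, 0.0083), GATA (0.791, 0.00997) and the NR2E half-site (0.899, 0.0273) as lower. With 100 bp windows (exact tests) these were proneural E-boxes (1.26, 0.0028) as higher and AGGTCA (0.656, 0.0194) as lower. Against other pooled peaks (Fisher's exact test) these were Twist (1.49, 9.97e-05) as higher, and AGGTCA (0.691, 0.00955), Sox (0.631, 0.0234) and proneural E-boxes (0.846, 0.048) as lower. With a replicate left out, the ratios were 0.978 to 1.20 for AP-1, 0.333 to 1.33 for Grainyhead, 0.975 to 0.996 for the NR2E half-site and 0.951 to 1.11 for clock E-boxes.

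With a replicate left out, 223 to 282 6-mers were higher and 314 to 417 lower, the lowest without replicate 1. Of the 56 named list genes with a promoter peak, 37 had one among the 1748 peaks and 34 in a 200 bp window. These sets are smaller by construction.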

Other observations

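All tests here were chosen after the result was seen. Genes for mitochondrial ribosomal proteins, of which mRpL41 and mRpS10 were among the strongest peaks, carried promoter peaks at 26 of 73 (35.6% against 19.1% of other genes; Fisher's exact test, adjusted p = 0.00137). The replicates had 24.7 ± 2.31 such genes (SD, n = 3). Against random lists matched on transcription start sites and gene length, which had 11.5%, the list passed a permutation test too (adjusted p = 0.0004). The families were chosen after the strongest peaks had been seen, and mRpL41 and mRpS10 were not left out. Neither p is therefore independent of that choice.

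Cuticle, chemoreceptor, cytochrome P450 and odorant-binding protein genes carried promoter peaks less often than other genes. Cuticle protein genes had 0 of 92 (Fisher's exact test, adjusted p = 1.84e-08), chemoreceptor genes 1 of 179 (1.67e-14), cytochrome P450 genes 2 of 85 (1.39e-05) and odorant-binding protein genes 1 of 51 (0.000966). Respiratory chain genes (19 of 84, Fisher's exact test, adjusted p = 0.405), aminoacyl-tRNA synthetase genes (8 of 32, adjusted p = 0.405) and translation initiation factor genes (12 of 44, adjusted p = 0.238) did not pass. Of these 8 families, 1 had promoter peaks more often and 4 less often than other genes.

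Peaks in the top list of a single replicate numbered 664, 749 and 969 in replicates 1, 2 and 3. Their promoter shares were 59.6%, 52.5% and 53.3%, and their coding exon shares 0.301%, 5.47% and 2.27%.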
